A study of Mus musculus with 8 samples.

How the data were processed

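RNA from sorted bone marrow stem cells of 8 libraries was extracted with RNeasy columns, amplified with the Ovation RNA-Seq v2 system and made into libraries with Nextera XT, per the labels' protocols. The mice carried Mx1-Cre and received 6 injections of polyI:C at 10 mg/kg every other day, and cells were collected 1 week after induction. Groups and replicate numbers were taken from the sample labels, with 2 libraries in each of wild type, Scribble null, Yap1 Taz null and the triple null. All files carry the same run and lane name, so no sequencing batch separates the groups.

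The authors deposited 1 table per library with a TPM value for each gene symbol, per the file headers, and each of these tables sums to 1000000 over 33641 symbols. The submitters' processing notes name TopHat, with no version, and the genome build mm10. The quantifier, the annotation and any filter are not given in the sources used here. TPM divides by transcript length and scales each library to a fixed total, so it keeps no depth, and a gene that takes a larger share lowers all others. Whether reads that map to several near-identical copies were shared, dropped or assigned to 1 copy is also not given in the sources used here. A further table of the whole series, deposited by the authors, holds linear values in a unit that its header does not name, for 28987 Ensembl identifiers. Its columns sum to between 818363 and 888261, it was used only as an alternative, and 27458 of its identifiers (94.725%) matched a symbol. All value columns were matched to a sample by name, and none was left out.

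Values were tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3, using a mean-variance trend and moderated variances. Genes with at least 1 TPM in at least 2 of the 8 libraries were kept, which left 16064. A single model with a mean for each of the 4 groups was fitted to all libraries, since the groups of a comparison alone leave fewer degrees of freedom for the spread, and had 4 residual and 4.002 prior degrees of freedom. The comparisons were each null genotype with wild type, the triple null with each other null genotype, and the departure of the triple null from the sum of the other changes. P-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, and genes under 0.05 were called. A fold change on the log2(TPM + 1) scale understates the change of genes with low values. An exact 0 in such a table can be a failed estimate, so a gene at 0 in a group is given as listed at 0, with the value of each library and no fold change.

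Gene lists were fixed before the data were examined. They hold 33 lists of cell cycle, stem cell, Hippo, polarity, signalling, metabolic and stress genes and of markers of other blood, endothelial and stromal cells, and 32 were tested, the sex-linked genes serving as a check of the libraries. Each was tested against all other genes with camera in limma at a preset correlation of 0.01 between genes, with adjustment over the 32 lists. Camera with an estimated correlation, and fry, which tests whether a list's genes move on balance in 1 direction, were alternatives. The genes named were also chosen by a rule fixed before the data were examined. It takes Scrib, Yap1 and Wwtr1 in every library, and the 10 largest changes per direction among genes called with no overlap between groups for comparisons with wild type, or 5 per direction for the others. It adds up to 4 members with the smallest p from each list, and it skips gene models without a name. Genes may be left out from the end of this order only, and any gene outside the rule is said to be chosen after its values were seen. Some genes that the rule names, and 1 of the lists, are not reported here.

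Symbols were matched to the GENCODE M21 annotation of the mouse genome build GRCm38, which is mm10. Of the tested genes 15598 (97.099%) matched, as 13506 protein-coding genes, 2013 pseudogenes and 79 others. Coordinates are from that annotation. The longest transcript of each gene was aligned to the others with BLAST 2.17.0, and 1268 tested genes had a near-identical copy, at 95% identity or more over 80% or more of the length. Values of these genes are uncertain where reads could be assigned to either copy.

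The model was tested on simulated data, with 200 of 16064 genes changed in each of 10 draws, and the values below are from a repeat with another random seed. For Scribble null against wild type it recovered 17.4% of genes changed by 1 on the log2 scale, 60.2% of those changed by 2 and 88.3% of those changed by 4, and 4.5% of its calls were false. For the departure from additivity it recovered 3.8%, 29.0% and 73.9%, with 4.0% of calls false. Small changes of single genes are therefore mostly missed with 2 libraries per group. Correlations of fold changes between comparisons that share the wild-type libraries were set beside 100 simulations of unchanged groups against the same controls.

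Alternatives chosen before the data were examined were a pseudocount of 0.1 or 5, no filter or a filter at 5 TPM, quantile normalization, scaling by the median ratio, the experiment number as a block, only the groups compared, limma without the trend, array weights, the table of the whole series, and each library left out in turn. Protein-coding genes only, genes with a near-identical copy left out, a gene length trend removed, and lists of protein-coding genes only were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.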

Results

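Messenger RNA was measured by sequencing in haematopoietic stem cells sorted from mouse bone marrow with SLAM surface markers. The mice carried Mx1-Cre, a recombinase switched on by interferon, and had received 6 injections of 10 mg/kg polyI:C, a double-stranded RNA mimic that induces interferon. Cells were collected 1 week after induction. The labels name 4 genotypes with 2 libraries each, which are wild type, Scribble null, Yap1 Taz null and a triple null for all 3 genes. Scribble is a scaffold of the basolateral polarity complex, and Yap1 and TAZ are transcriptional co-activators restrained by the Hippo kinases. Each library was given as TPM, transcript abundance scaled to a fixed total per library, over 33641 gene symbols, of which 14024 to 14970 reached 1 TPM. Correlation of log2 values across genes was 0.963 between the wild-type libraries, 0.953 between those labelled Scribble null, 0.957 for Yap1 Taz null and 0.965 for the triple null. The highest correlation of each library with one of another genotype was 0.945 to 0.958, and for Scribble null 2, at 0.958, it was above that with its replicate. TPM keeps no sequencing depth, so the depth behind each value is unknown. Nothing in the labels says that the 2 libraries of a genotype came from separate animals, and the p-values then measure only the spread between these libraries, which may be technical.

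No targeted gene was called lower in the libraries whose labels name it, although Scrib was lower in both Scribble null libraries than in both wild-type ones. Scrib (mm10 chromosome 15, 76047158 to 76069784) stood at 8.74 ± 0.775 TPM in wild type and 6.94 ± 0.970 TPM in the libraries labelled Scribble null (mean ± SD, n = 2), a log2 difference of −0.30 with an adjusted p of 0.669. In the libraries labelled Yap1 Taz null, which do not name Scrib, it was 7.98 and 7.32 TPM, also below both wild-type values of 8.19 and 9.29 TPM. In the libraries labelled triple null it was 14.5 and 7.54 TPM. Yap1 (chromosome 9, 7931999 to 8004596) was 2.08 ± 0.105 TPM in wild type, 2.13 and 6.63 TPM in the libraries labelled Yap1 Taz null and 2.31 ± 0.0866 TPM in those labelled triple null. Wwtr1 (chromosome 3, 57455649 to 57575910), the gene of the TAZ protein, was 0.959 ± 0.323 TPM in wild type, 1.12 ± 0.0388 TPM in Yap1 Taz null libraries and 1.35 ± 0.811 TPM in triple null libraries. Its level in the libraries labelled Scribble null was 4.62 ± 1.000 TPM, a log2 difference of 1.52 from wild type with an adjusted p of 0.101. The symbol Taz in the files is tafazzin, an X-linked mitochondrial gene that was not a target. Yap1 and Wwtr1 were so low in wild type that even a full loss could hardly have been called on the log2(TPM + 1) scale. A level summed over a whole gene also cannot show the loss of single exons, so these values do not check the labels. Every direction below is between libraries as labelled.

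**Figure D1:**
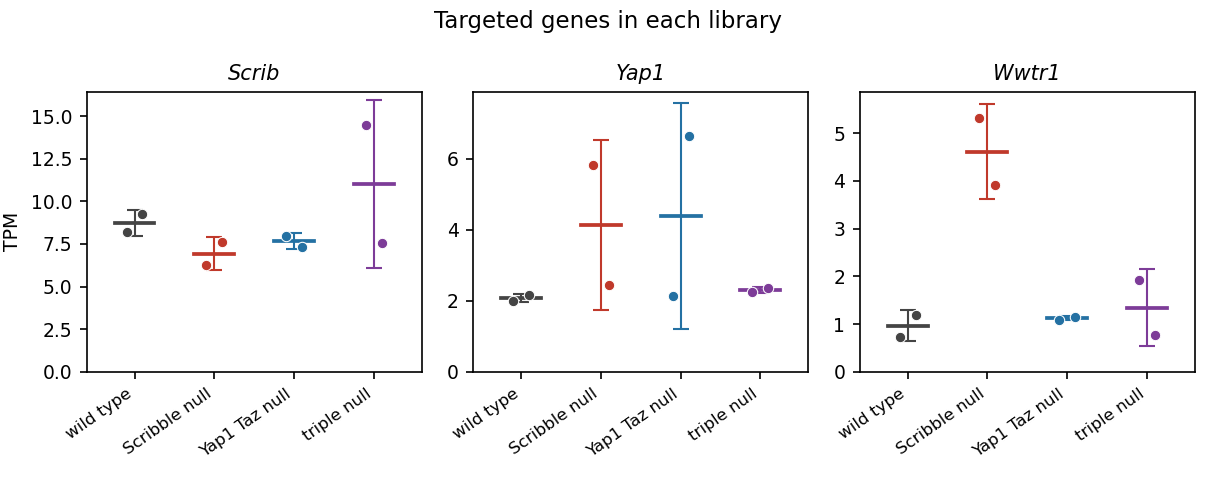
TPM of Scrib, Yap1 and Wwtr1 (vertical axes, linear, from 0) in each library by labelled genotype (horizontal axes). Points are libraries, bars are means and whiskers are SD (n = 2), and none of the 3 genes fell past the test in the libraries whose labels name it. For Yap1 and Wwtr1, low in wild type, even a full loss could hardly have been called.

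The first comparison asked what loss of Scribble changes. In the libraries labelled Scribble null, the MHC class II genes H2-Aa and H2-Ab1, which present antigen peptides, fell from 1454 ± 74.2 to 116 ± 15.6 TPM and from 630 ± 89.7 to 77.5 ± 9.0 TPM. Cd74, the class II invariant chain, fell from 721 ± 66.3 to 109.6 ± 4.43 TPM. Pf4, a platelet chemokine, fell from 887 ± 100.3 to 96.9 ± 2.80 TPM, a log2 change of −3.18 with an adjusted p of 0.000333. Egr1, a zinc-finger factor of the immediate early response, rose from 509.7 ± 7.07 to 1110.3 ± 51.2 TPM. Skil, a repressor of SMAD signalling, rose from 51.3 ± 1.74 to 146 ± 6.01 TPM. Of 16064 genes tested, 95 were higher and 114 lower, and 159 of these 209 were protein-coding, 46 pseudogenes and 47 had a near-identical copy elsewhere in the genome. Scaling each library by its median ratio changed the split to 57 higher and 189 lower. The groups did not overlap for 48.879% of genes, against 33.3% by chance.

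The genes named for the size of their rise began with BC002163, a pseudogene with 1 near-identical copy, which rose from 0.721 ± 0.0440 to 31.0 ± 1.56 TPM. Vldlr, a lipoprotein receptor, rose from 3.06 ± 0.487 to 23.4 ± 9.29 TPM. Kcnip3, the lectin-like receptor gene Klrb1a, the class II chaperone subunit H2-Ob and the integrin subunit Itgam rose by 2.42, 2.26, 2.19 and 2.18 on the log2(TPM + 1) scale, on which all fold changes here are given. Spag6l, the ferritin autophagy receptor Ncoa4 and Sbf2 rose by 2.13, 2.07 and 1.98. Among gene models with a name, the largest falls were in copies of ribosomal protein genes, whose values are uncertain where reads could be shared with other copies. Rpl3-ps1, Rps13-ps1, Rpl34-ps1 and Rpl35a-ps2 had log2 changes of −6.86, −5.94, −5.76 and −5.73, with Rpl35a-ps3, Rpl35a-ps4 and Rpl35a-ps6 carrying the same values as Rpl35a-ps2. Summed with near-identical copies, the log2 changes were −0.36, −0.37, −5.03 and −0.69, and that of BC002163 was 0.24. The sum for Rpl34-ps1 holds 5 members and leaves out Rpl34 itself, while those of Rpl3-ps1, Rps13-ps1 and Rpl35a-ps2 take in Rpl3, Rps13 and Rpl35a. In a wider family of 6, matched over at least 50% of the length, Rpl34-ps1 fell by 833 TPM and the other members together rose by 276 TPM. Rpl10-ps3 fell by 5.09 and H2-Ea-ps (chromosome 17, 34341959 to 34344645) fell from 56.9 ± 10.5 to 0.798 ± 0.333 TPM.

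Cell division genes were lower as groups. Counts of list members called are given below as higher and lower, in that order. The 35 measured genes of G1/S and DNA replication had a median log2 change of −0.63 (0 and 6 over all genes, 0 and 17 adjusted over the list alone), led by Gins1 and Gins2 of the replicative helicase, the cyclin gene Ccnd1 and the ribonucleotide reductase subunit Rrm2 (adjusted p = 1.54e-16, adjusted p = 0.0816 with an estimated correlation). Gins1 went from 50.4 ± 4.92 to 12.5 ± 6.85 TPM and Ccnd1 from 41.9 ± 8.40 to 16.7 ± 1.13 TPM. The 32 genes of G2/M and mitosis had a median of −0.51 (0 and 2 over all genes, 1 and 11 adjusted over the list alone), with the checkpoint kinase Ttk at −1.45 and Cdca8 at −0.90 (adjusted p = 2.25e-12, adjusted p = 0.0816 with an estimated correlation). The 37 genes of oxidative phosphorylation had a median of −0.47 (0 and 1 over all genes, 0 and 17 adjusted over the list alone), and the ATP synthase subunit Atp5g1 fell from 275 ± 9.05 to 136 ± 3.71 TPM (adjusted p = 5.04e-14, adjusted p = 0.0307 with an estimated correlation). The 54 ribosomal protein genes had a median of −0.26 (1 and 0 over all genes, 4 and 19 adjusted over the list alone), although Rpl30 itself rose by 0.61 (adjusted p = 6.73e-12, adjusted p = 0.160 with an estimated correlation). MYC and ribosome biogenesis genes (31) had a median of −0.19, with none called over all genes and Npm1 alone lower adjusted over the list alone (adjusted p = 0.000421, adjusted p = 0.160 with an estimated correlation).

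Interferon-induced genes were also lower. Of 42 measured, 1 was higher and 9 lower over all genes, and 3 and 16 adjusted over the list alone, with a median of −0.36 (adjusted p = 9.59e-11, adjusted p = 0.0307 with an estimated correlation). The interferon-inducible GTPases Gbp6, Iigp1 and Igtp had log2 changes of −2.62, −1.97 and −1.56. The 14 monocyte, macrophage and dendritic markers differed in sign by measure, with a median of 0.06, a mean of −0.57 and a test that put the list lower (adjusted p = 0.0157, adjusted p = 0.157 with an estimated correlation). Its members called lower were H2-Aa, H2-Ab1 and Cd74, and over the list alone 3 were higher and 5 lower. Lyz2, the most abundant member besides the class II genes and Cd74, was 212 and 256 TPM in wild type and 238 and 205 TPM in the libraries labelled Scribble null.

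Immediate early and AP-1 genes rose as a group, with Egr1, Fosb and Klf6 called and a median over 28 genes of 0.29 (3 and 0 over all genes, 10 and 0 adjusted over the list alone; adjusted p = 0.000286, adjusted p = 0.157 with an estimated correlation). Fosb went from 321 ± 8.17 to 618 ± 38.0 TPM. Quiescence genes and cell cycle inhibitors had a median of 0.34 over 23 (2 and 0 over all genes, 6 and 0 adjusted over the list alone), with Egr1 and the glucocorticoid-induced Tsc22d3 called (adjusted p = 0.000776, adjusted p = 0.135 with an estimated correlation). Stem cell identity genes had a median of 0.28 over 30 (0 and 0 over all genes, 4 and 2 adjusted over the list alone), led by Ly6a at −1.06 and Trim47 at 0.79, neither past the test (adjusted p = 0.0335, adjusted p = 0.227 with an estimated correlation). Granulocyte and myeloid progenitor markers had a median of 0.80 over 6, with the protease gene Prtn3 rising from 129 ± 16.2 to 344 ± 115 TPM and the cytokine receptor Csf3r from 54.8 ± 2.73 to 116 ± 1.59 TPM (2 and 0 over all genes, 2 and 0 adjusted over the list alone; adjusted p = 0.0339, adjusted p = 0.160 with an estimated correlation). Erythroid markers had a median of −0.48 over 15 (0 and 0 over all genes, 0 and 3 adjusted over the list alone; adjusted p = 0.000780, adjusted p = 0.157 with an estimated correlation), and megakaryocyte markers one of −0.31 over 20, with Pf4 lower and the integrin subunit Itgb3 higher by 1.48 (1 and 1 over all genes, 2 and 3 adjusted over the list alone; adjusted p = 0.00101, adjusted p = 0.135 with an estimated correlation). Hippo cascade genes had a median of 0.30 over 30, none called over all genes and 3 higher adjusted over the list alone (adjusted p = 0.0347, adjusted p = 0.160 with an estimated correlation).

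In this comparison 14 of 32 fixed lists passed camera, a test of each list against all other genes, and 2 did with an estimated correlation. The median log2 change of all genes was 0.15 here, 0.14 for Yap1 Taz null and 0.12 for the triple null, and list medians are to be read against it. The count of 209 genes fell to 47 and 64 without wild type 1 and 2, 64 without Scribble null 1, 105 and 112 without Yap1 Taz null 1 and 2, and 91 without either triple null library. It was 221 without Scribble null 2, where 113 of the 209 were also called.

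**Figure D2:**
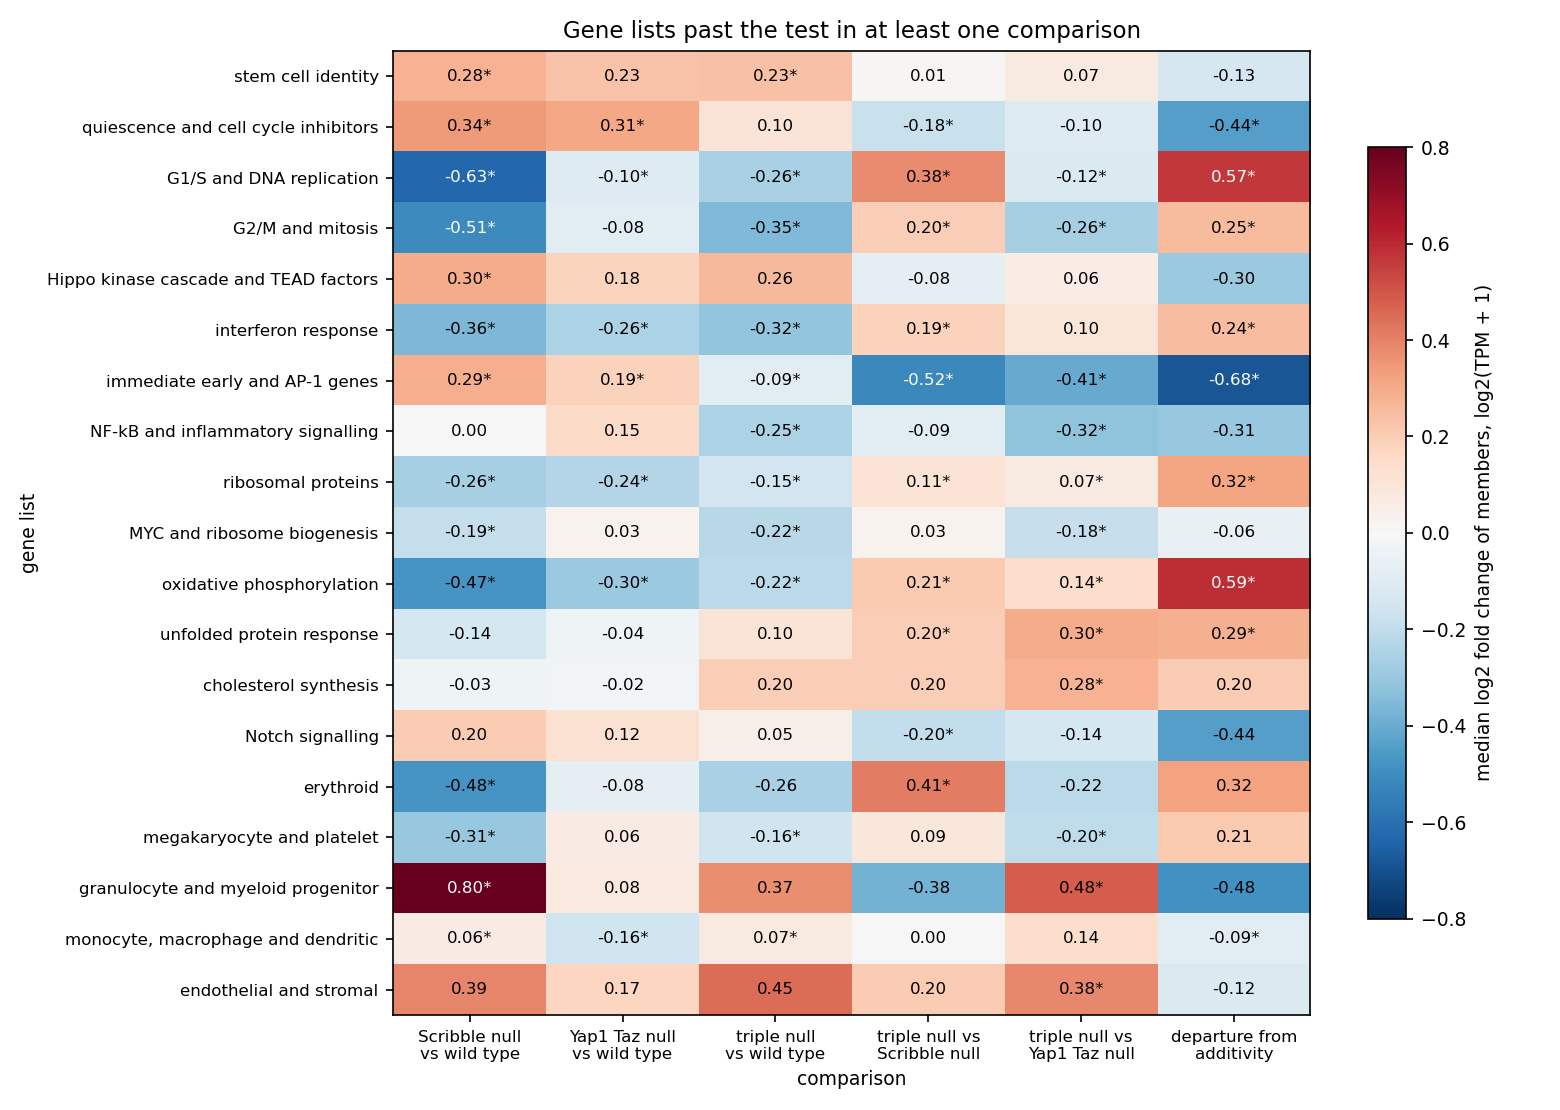
Median log2(TPM + 1) change of each gene list (vertical axis) in the comparisons (horizontal axis), as colour with the value printed and an asterisk where the list passed camera. In the comparison of Scribble null with wild type, G1/S genes stand at −0.63 and oxidative phosphorylation at −0.47.

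The second comparison asked what joint loss of Yap1 and Taz changes. In the libraries labelled Yap1 Taz null, Rps3a1, which encodes a protein of the small ribosomal subunit, fell from 3552 ± 145 to 248 ± 24.7 TPM. Its near-identical pseudogenes Rps3a2 and Rps3a3 rose from 9.94 ± 3.53 to 1332 ± 137 TPM and from 33.5 ± 0.950 to 749 ± 94.8 TPM. Summed over the 6 copies the level was 3609 TPM in wild type and 2337 TPM in these libraries. The kallikrein gene Klk1b22 rose from 1.85 ± 0.162 to 147 ± 35.3 TPM. H2-Aa, Cd74 and Pf4 fell here too, to 246 ± 16.96, 136 ± 44.5 and 217 ± 8.04 TPM. Egr1 rose to 940 ± 97.2 and Skil to 140.1 ± 0.726 TPM. Of 16064 genes, 76 were higher and 83 lower, with 113 of the 159 protein-coding, 42 pseudogenes and 41 with a near-identical copy. Median-ratio scaling gave 38 higher and 94 lower, and quantile normalization 53 and 94. Groups did not overlap for 46.576% of genes, against 33.3% by chance.

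**Figure D3:**
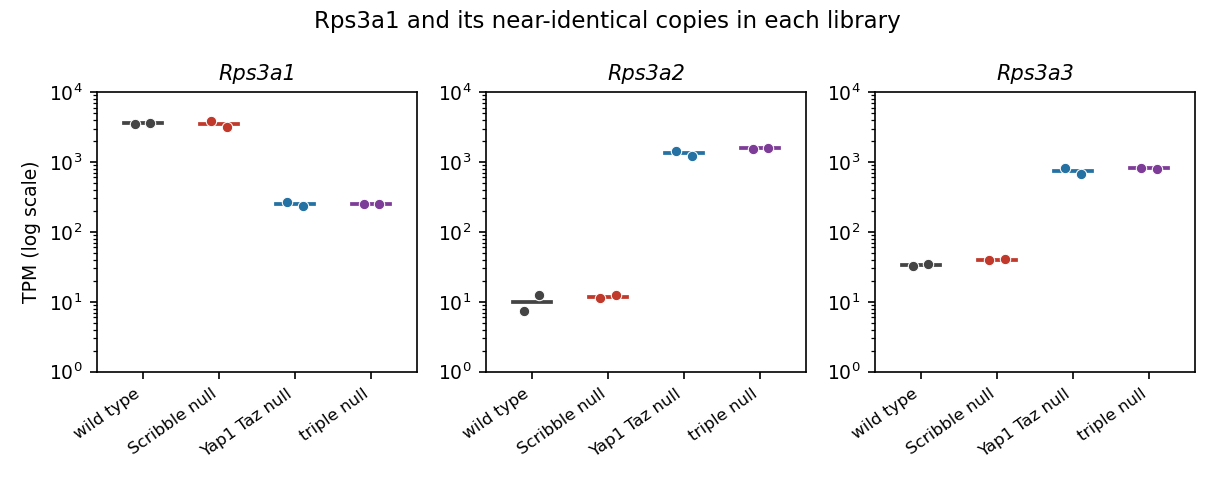
TPM of Rps3a1, Rps3a2 and Rps3a3 (vertical axes, log scale from 1 to 10000) in each library by labelled genotype (horizontal axes). Points are libraries and bars are means (n = 2), and Rps3a1 is low where Rps3a2 and Rps3a3 are high, in the libraries labelled Yap1 Taz null and triple null.

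Among gene models with a name, the largest rise after Rps3a2, Klk1b22 and Rps3a3 was in the immunoglobulin joining segment Ighj4, listed at 0 in both wild-type libraries and at 12.4 and 12.0 TPM in those labelled Yap1 Taz null. Eno1b, a near copy of the glycolytic enolase gene, and the complement protease gene Masp2 rose by 3.40 and 2.99. Cdk5rap1, a transfer RNA modifying enzyme, rose from 5.40 ± 0.820 to 49.5 ± 4.64 TPM, and Zfp69 from 2.54 ± 0.739 to 18.8 ± 0.598 TPM. Tma7-ps was listed at 0 in wild type and at 6.78 and 5.68 TPM here. With near-identical copies added, Eno1b and Tma7-ps had log2 changes of −0.38 and −0.42. The BMP type I receptor gene Bmpr1a rose from 0.485 ± 0.0522 to 6.41 ± 0.0193 TPM. Rpl3-ps1, Rps13-ps1 and Rpl34-ps1 fell, with log2 changes of −6.38, −6.01 and −5.90. Rpl35a-ps2 and the 3 copies with its values fell by 5.67, H2-Ea-ps fell by 5.49, and the class I-like gene H2-T3 fell from 122 ± 25.5 to 4.76 ± 2.61 TPM.

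Oxidative phosphorylation genes were lower as a group, with a median of −0.30 and the cytochrome oxidase subunits Cox7a2 and Cox5a at −0.96 and −0.81 (0 and 2 over all genes, 0 and 4 adjusted over the list alone; adjusted p = 1.59e-12, adjusted p = 0.0365 with an estimated correlation). Interferon-induced genes had a median of −0.26 (0 and 7 over all genes, 1 and 12 adjusted over the list alone; adjusted p = 6.66e-09, adjusted p = 0.0365 with an estimated correlation), with Iigp1, Igtp and Gbp4 lower by log2 changes of −1.66, −1.56 and −1.74. Ribosomal protein genes had a median of −0.24, though the only member called, Rps18, rose by 0.81 (1 and 0 over all genes, 1 and 0 adjusted over the list alone; adjusted p = 1.32e-11, adjusted p = 0.384 with an estimated correlation). The G1/S genes had a median of −0.10 with no member called either way (adjusted p = 0.00112, adjusted p = 0.448 with an estimated correlation). Monocyte, macrophage and dendritic markers had a median of −0.16, with H2-Aa, H2-Ab1 and Cd74 lower and the dendritic cell receptor Clec9a higher, from 3.16 ± 1.03 to 13.8 ± 0.473 TPM (1 and 3 over all genes, 1 and 4 adjusted over the list alone; adjusted p = 0.00112, adjusted p = 0.183 with an estimated correlation). Lyz2 was 213 and 176 TPM in these libraries. Immediate early genes had a median of 0.19 (1 and 0 over all genes, 7 and 0 adjusted over the list alone; adjusted p = 0.0304, adjusted p = 0.448 with an estimated correlation). Quiescence genes had a median of 0.31, with Egr1 and the nuclear receptor Nr4a2 higher and the repressor Gfi1 lower, from 12.9 ± 4.76 to 1.86 ± 0.326 TPM (2 and 1 over all genes, 5 and 1 adjusted over the list alone; adjusted p = 0.0320, adjusted p = 0.384 with an estimated correlation).

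The Y-linked genes Eif2s3y, Kdm5d and Ddx3y fell from 51.0 ± 7.24 to 4.39 ± 0.334 TPM, from 45.2 ± 3.27 to 6.28 ± 1.46 TPM and from 20.5 ± 3.43 to 2.26 ± 0.309 TPM in the libraries labelled Yap1 Taz null, and were not low in any other group. Uty was 10.6 and 20.02 TPM there and 25.2 and 25.8 TPM in wild type. Of 6 X-linked genes known to escape X inactivation, 5 were higher in both of these libraries than the mean of the other 6 libraries, with a median log2 difference of 0.21. Only Kdm6a, at 50.9 and 79.1 TPM, and Eif2s3x, at 102 and 87.3 TPM, were above every other library in both. The labels used here give no sex, and a difference in sex would not be separated from genotype in any comparison that uses these libraries, the departure from additivity included. Camera called 7 of 32 lists here, 2 of them also with an estimated correlation. The 159 genes fell to 53 and 59 without wild type 1 and 2, 66 and 65 without Yap1 Taz null 1 and 2, and 96 and 94 without triple null 1 and 2.

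The third comparison asked what loss of all 3 genes changes. In the libraries labelled triple null, Rps3a1 stood at 247 ± 0.482 TPM, a log2 change from wild type of −3.84, and Rps3a2 and Rps3a3 at 1560 ± 19.7 and 808 ± 20.1 TPM, rises of 7.20 and 4.55, with 2620 TPM over the 6 copies. H2-Aa, H2-Ab1, Cd74 and Pf4 fell to 307 ± 3.71, 160.4 ± 7.36, 286 ± 3.59 and 179 ± 61.6 TPM. Cyr61, a matricellular gene induced by Yap1, fell from 33.0 ± 3.17 to 8.18 ± 2.38 TPM (log2 −1.91, adjusted p = 0.0143). Dock11, an exchange factor for Cdc42, had a log2 change of −1.16, beside −1.23 in Yap1 Taz null and −0.21 in Scribble null. Arhgdib rose by 0.76. Of 16064 genes, 36 were higher and 57 lower, with 53 of the 93 protein-coding, 35 pseudogenes and 35 with a near-identical copy. Median-ratio scaling gave 25 higher and 65 lower. Groups did not overlap for 45.132% of genes, against 33.3% by chance.

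Ighj4 was listed at 0 in wild type and at 52.1 and 292 TPM in the libraries labelled triple null. Other immunoglobulin genes were also uneven between these libraries, with Igkc at 55.6 and 879 TPM, Ighm at 234 and 8.75 TPM and Jchain at 8.004 and 54.7 TPM, against 8.44, 2.71 and 0.946 TPM on average in wild type. Tma7-ps was listed at 0 in wild type and at 15.1 and 11.8 TPM here. Eno1b, Masp2, the disintegrin gene Adam11, Amd2 and the nucleoside transporter Slc28a2 rose by 3.45, 2.65, 2.32, 2.28 and 2.24. Summed with their near-identical copies, Eno1b, Amd2, Slc28a2 and Tma7-ps had log2 changes of −0.45, 0.21, 1.91 and −0.13. Rpl3-ps1, Rpl34-ps1 and Rps13-ps1 fell, with log2 changes of −6.64, −6.29 and −5.66. Rpl35a-ps2 and the 3 copies with its values fell by 5.60, H2-Ea-ps fell by 5.07 and H2-T3 fell by 4.58.

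Cell cycle genes were lower as groups although no single member was called. G1/S genes had a median of −0.26 (adjusted p = 5.53e-09, adjusted p = 0.152 with an estimated correlation), with Rrm2 at −0.84, and G2/M genes one of −0.35 (adjusted p = 5.53e-09, adjusted p = 0.152 with an estimated correlation), with Cdca8 at −0.71. Adjusted over the list alone, none passed in either. Oxidative phosphorylation had a median of −0.22 (0 and 0 over all genes, 0 and 0 adjusted over the list alone; adjusted p = 5.53e-09, adjusted p = 0.0743 with an estimated correlation). Interferon-induced genes had a median of −0.32, with Igtp, Gbp6 and Iigp1 at −1.29, −1.5 and −1.13 (0 and 4 over all genes, 0 and 10 adjusted over the list alone; adjusted p = 7.33e-08, adjusted p = 0.0743 with an estimated correlation). Ribosomal protein genes had a median of −0.15, while Rps18 rose by 0.87 (1 and 0 over all genes, 2 and 0 adjusted over the list alone; adjusted p = 7.33e-08, adjusted p = 0.260 with an estimated correlation). MYC and ribosome biogenesis had a median of −0.22 (0 and 0 over all genes, 0 and 0 adjusted over the list alone; adjusted p = 3.54e-05, adjusted p = 0.172 with an estimated correlation), and NF-kB and inflammatory genes one of −0.25, led by Tnf at −1.78 (0 and 0 over all genes, 0 and 1 adjusted over the list alone; adjusted p = 0.00155, adjusted p = 0.168 with an estimated correlation).

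The markers of monocytes, macrophages and dendritic cells again differed in sign by measure, with a median of 0.07, a mean of −0.45 and a test that put them lower (0 and 3 over all genes, 0 and 4 adjusted over the list alone; adjusted p = 0.00137, adjusted p = 0.152 with an estimated correlation). Lyz2 was 292 and 238 TPM. Stem cell identity genes had a median of 0.23, with the cytokine receptor Kit at 0.70, not past the test over all genes (0 and 0 over all genes, 7 and 1 adjusted over the list alone; adjusted p = 0.00220, adjusted p = 0.189 with an estimated correlation). Immediate early genes had a median of −0.09 (0 and 0 over all genes, 2 and 4 adjusted over the list alone; adjusted p = 0.00242, adjusted p = 0.199 with an estimated correlation). Megakaryocyte markers had a median of −0.16, with Pf4 the member called (0 and 1 over all genes, 1 and 1 adjusted over the list alone; adjusted p = 0.00727, adjusted p = 0.172 with an estimated correlation). Camera called 11 of 32 lists, and 0 with an estimated correlation, where 8 lists had an unadjusted p under 0.05 and fry called 11. The 93 genes fell to 39 and 48 without wild type 1 and 2 and to 46 and 45 without triple null 1 and 2.

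Across the 3 comparisons with wild type, 47 genes were called in all, 8 higher and 39 lower, and each in 1 direction throughout. Of these, 24 were protein-coding and 21 had a near-identical copy. The following were chosen after their values were seen. The class I genes H2-D1 and H2-K1 stood at 1890 ± 109 and 3319 ± 148 TPM in wild type and at 878 and 1787 TPM on average in libraries labelled Scribble null, 837 and 1862 TPM in Yap1 Taz null and 843 and 1933 TPM in triple null. The non-classical class I gene H2-T23 was higher, at 70.9 TPM in wild type against 169.7, 183 and 209 TPM. The aspartic protease gene Ctse was lower, at 161 TPM against 34.9, 45.7 and 32.2 TPM, and the architectural chromatin gene Hmga1 higher, at 55.1 TPM against 123, 136 and 135 TPM. Within chromosome 17 from 30 to 40 Mb, which holds the MHC, 15 of 221 tested genes were called in at least 2 of the 3 comparisons, against 95 of 15843 elsewhere.

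**Figure D4:**
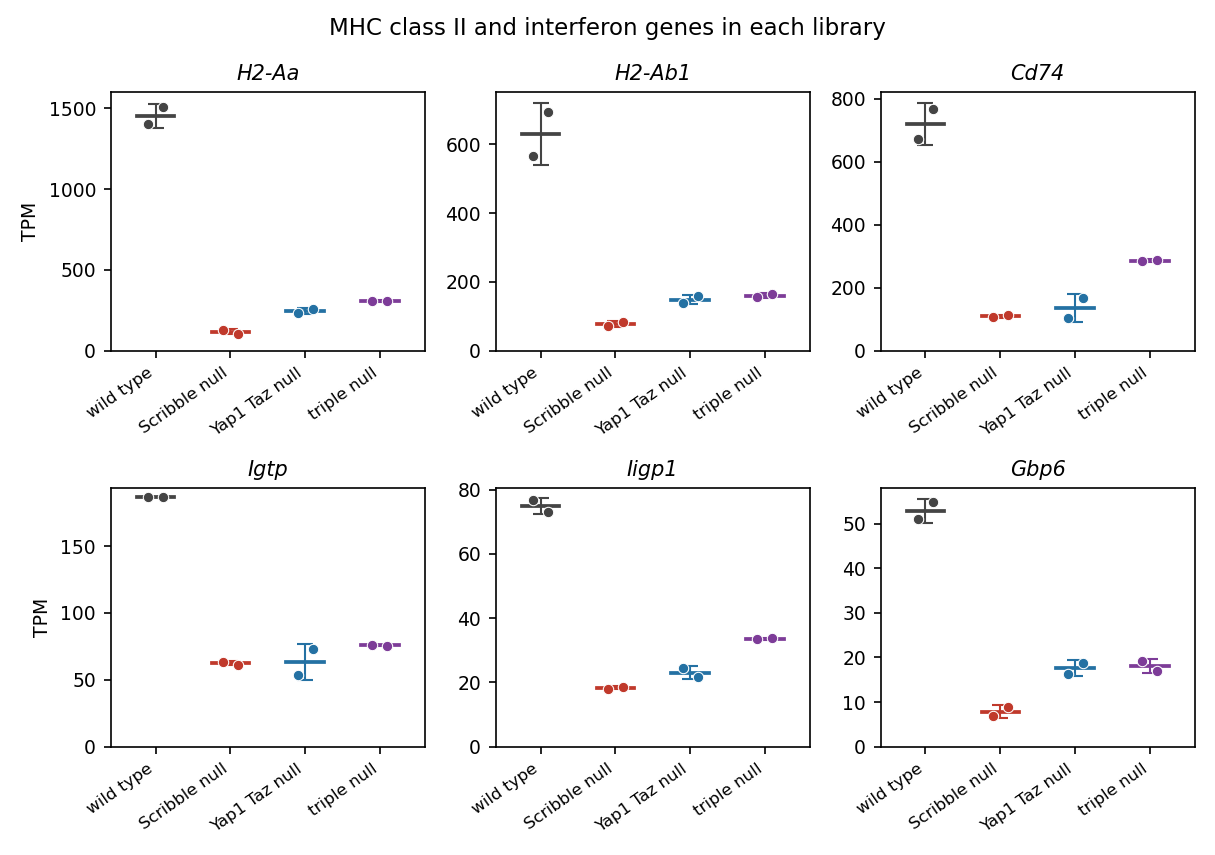
TPM of interferon-induced and MHC genes (vertical axes, linear, from 0) in each library by labelled genotype (horizontal axes). Points are libraries, bars are means and whiskers are SD (n = 2), with H2-Aa at 1454 TPM in wild type and 116, 246 and 307 TPM in the Scribble null, Yap1 Taz null and triple null libraries.

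Scribble null and Yap1 Taz null libraries shared 23 genes higher and 56 lower than wild type. For Scribble null and triple null these were 12 and 47, and for Yap1 Taz null and triple null 23 and 43. All were called against the same 2 wild-type libraries, which alone makes such lists overlap. Across 16064 genes, which are not independent replicates, the fold changes correlated at 0.598, 0.607 and 0.611 for the 3 pairs, where unchanged groups against the same controls gave 0.499 in 100 simulations. The covariances were 0.217, 0.209 and 0.203, against 0.0967 simulated, which leaves differences of 0.120, 0.112 and 0.106. Without wild type 2 the covariances were 0.380, 0.373 and 0.363, with a pseudocount of 0.1 they were 0.466, 0.462 and 0.453, and with 5 they were 0.106, 0.0999 and 0.0987, and no simulated value was computed for these. The 2 wild-type libraries were not split between the comparisons, so part of the excess may come from the shared controls. Comparisons with no library in common did not correlate in this way, at −0.024 for Scribble null against wild type with triple null against Yap1 Taz null, and −0.044 for Yap1 Taz null against wild type with triple null against Scribble null. A change common to all null genotypes cancels in triple null against another null. These values therefore do not tell such a change from an effect of the shared controls.

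The triple null was next compared with Scribble null, which asked what further loss of Yap1 and Taz changes where Scribble is already lost. In the libraries labelled triple null, Rps3a1 was lower than in Scribble null by a log2 change of −3.81, and Rps3a2 and Rps3a3 were higher by 6.93 and 4.30. The growth factor gene Gdf15 fell from 46.7 ± 1.63 to 12.4 ± 2.68 TPM, and the transcription factor genes Hey1 and Bhlhe40 fell from 83.3 ± 21.9 to 28.5 ± 1.16 TPM and from 162 ± 13.9 to 59.4 ± 0.0321 TPM. Skil fell from 146 to 58.1 ± 0.699 TPM, and H2-Aa rose by 1.40. Hist1h2al and Eno1b, which have near-identical copies, rose by 3.83 and 3.72. Summed with its copies, Hist1h2al was at 80.5 ± 41.0 TPM in Scribble null and 81.9 ± 18.5 TPM in the triple null. The sum for Eno1b was lower in the triple null, at 115.9 ± 3.32 TPM against 132.5 ± 9.12 TPM. Tma7-ps was listed at 0 in Scribble null. BC002163 was listed at 0 in both triple null libraries and at 29.9 and 32.1 TPM in Scribble null. In all, 18 genes were higher and 16 lower, of which 16 were protein-coding, 17 pseudogenes and 16 with a near-identical copy. Groups did not overlap for 40.096% of genes, against 33.3% by chance.

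Immediate early genes were lower in the triple null libraries than in Scribble null, with a median of −0.52 and the heat shock gene Hspa1a at −0.80 (0 and 1 over all genes, 0 and 16 adjusted over the list alone; adjusted p = 3.08e-15, adjusted p = 0.116 with an estimated correlation). Notch genes had a median of −0.20, with the targets Hes1 and Hey1 at −1.0 and −1.49 (0 and 2 over all genes, 0 and 2 adjusted over the list alone; adjusted p = 0.0133, adjusted p = 0.423 with an estimated correlation). Quiescence genes had a median of −0.18, with no member called over all genes (0 and 0 over all genes, 0 and 6 adjusted over the list alone; adjusted p = 0.00101, adjusted p = 0.167 with an estimated correlation). G1/S genes were higher, with a median of 0.38 (0 and 0 over all genes, 1 and 0 adjusted over the list alone; adjusted p = 5.57e-07, adjusted p = 0.230 with an estimated correlation), and G2/M genes had one of 0.20 (0 and 0 over all genes, 0 and 0 adjusted over the list alone; adjusted p = 0.00827, adjusted p = 0.408 with an estimated correlation). Interferon-induced genes had a median of 0.19, led by Isg20 at 0.98, not past the test over all genes (0 and 0 over all genes, 6 and 0 adjusted over the list alone; adjusted p = 0.00119, adjusted p = 0.167 with an estimated correlation). Oxidative phosphorylation and ribosomal proteins had medians of 0.21 (adjusted p = 0.000314, adjusted p = 0.167 with an estimated correlation) and 0.11 (adjusted p = 0.00306, adjusted p = 0.444 with an estimated correlation), with no member called over all genes or adjusted over the list alone. The unfolded protein response had a median of 0.20, led by the chaperone Hsp90b1 at 0.67 (0 and 0 over all genes, 2 and 0 adjusted over the list alone; adjusted p = 0.00694, adjusted p = 0.254 with an estimated correlation), and erythroid markers one of 0.41 (0 and 0 over all genes, 2 and 0 adjusted over the list alone; adjusted p = 0.0333, adjusted p = 0.407 with an estimated correlation). Camera called 10 of 32 lists, and 0 with an estimated correlation, where 6 had an unadjusted p under 0.05 and fry called 4. The 34 genes became 21 and 61 without Scribble null 1 and 2, and 20 and 19 without triple null 1 and 2.

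The triple null was also compared with Yap1 Taz null, which asked what further loss of Scribble changes where Yap1 and Taz are already lost. The Y-linked genes Eif2s3y, Ddx3y and Kdm5d were higher in the triple null libraries, by 3.54, 3.23 and 2.80, which repeats their low level in the libraries labelled Yap1 Taz null. Rab6b, a GTPase of Golgi transport, rose from 5.32 ± 0.888 to 20.8 ± 0.665 TPM, and Procr, the endothelial protein C receptor used to mark stem cells, from 65.7 ± 6.42 to 146 ± 4.20 TPM. Klk1b22 fell from 147 to 1.88 ± 0.509 TPM, Zfp69 and Zfp990 had log2 changes of −2.29 and −2.24, and BC002163 was listed at 0 in the triple null. Cyr61 fell from 30.0 ± 2.68 to 8.18 ± 2.38 TPM, with log2 changes in Vegfa and Skil of −1.49 and −1.26. In all, 11 genes were higher and 18 lower, 20 of them protein-coding, 7 pseudogenes and 6 with a near-identical copy. Median-ratio scaling gave 12 higher and 12 lower. Groups did not overlap for 40.027% of genes, against 33.3% by chance.

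Immediate early genes were lower here too, with a median of −0.41 and Hspa1a at −0.85 (0 and 1 over all genes, 0 and 10 adjusted over the list alone; adjusted p = 6.46e-09, adjusted p = 0.233 with an estimated correlation). NF-kB and inflammatory genes had a median of −0.32, led by Birc3 at −0.94, not past the test over all genes (0 and 0 over all genes, 0 and 4 adjusted over the list alone; adjusted p = 0.00934, adjusted p = 0.233 with an estimated correlation). Granulocyte markers had a median of 0.48, led by Gfi1 at 2.14 (0 and 0 over all genes, 1 and 0 adjusted over the list alone; adjusted p = 0.00934, adjusted p = 0.233 with an estimated correlation). Megakaryocyte markers had a median of −0.20 (0 and 0 over all genes, 0 and 2 adjusted over the list alone; adjusted p = 0.0428, adjusted p = 0.234 with an estimated correlation), and the unfolded protein response one of 0.30 (0 and 0 over all genes, 1 and 1 adjusted over the list alone; adjusted p = 0.0367, adjusted p = 0.234 with an estimated correlation). G2/M, MYC and G1/S genes had medians of −0.26 (adjusted p = 0.000368, adjusted p = 0.233 with an estimated correlation), −0.18 (adjusted p = 0.00934, adjusted p = 0.265 with an estimated correlation) and −0.12 (adjusted p = 0.0367, adjusted p = 0.376 with an estimated correlation). Cholesterol synthesis, endothelial and stromal, oxidative phosphorylation and ribosomal protein genes had medians of 0.28 (adjusted p = 0.0183, adjusted p = 0.233 with an estimated correlation), 0.38 (adjusted p = 0.0183, adjusted p = 0.233 with an estimated correlation), 0.14 (adjusted p = 0.0217, adjusted p = 0.233 with an estimated correlation) and 0.07 (adjusted p = 0.0234, adjusted p = 0.459 with an estimated correlation). In these last 7 lists no member was called over all genes or adjusted over the list alone. Camera called 12 of 32 lists, and 0 with an estimated correlation, where 5 had an unadjusted p under 0.05 and fry called 2. Without Yap1 Taz null 1 or 2 the lists fell to 6 and 3, without triple null 1 to 6, and without Yap1 Taz null 2 the median of the ribosomal list turned to −0.003. The 29 genes fell to 13 without either wild-type library, 10 and 9 without Yap1 Taz null 1 and 2, and 19 and 11 without triple null 1 and 2.

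The last comparison asked directly whether the change with loss of Scribble differs when Yap1 and Taz are also lost, as the triple null change minus the sum of the other 2 changes from wild type on the log2 scale. Skil rose in the Scribble null and Yap1 Taz null libraries and stood at 58.1 ± 0.699 TPM in the triple null against 51.3 ± 1.74 TPM in wild type, a departure of −2.75 (adjusted p = 0.000458). Egr1 departed by −1.44 and Nr4a2 by −1.59. The interferon-induced Iigp1, Gbp6 and Igtp departed upward, by 2.5, 2.66 and 1.84. Klk1b22, Zfp69, Clec9a and Zfp990, whose highest levels were in the libraries labelled Yap1 Taz null, departed by −5.86, −3.95, −3.15 and −2.97. BC002163, listed at 0 in the triple null, was also called. Rpl3-ps1, Rps13-ps1 and Rpl35a-ps2, low in each null genotype by a similar amount, departed by 6.60, 6.29 and 5.81. Rpl10-ps3, called lower in Scribble null only and at 595 and 152 TPM in the triple null, departed by 6.79. Of 102 genes called, 60 were above and 42 below the sum, and 65 and 28 after median-ratio scaling. Among them 69 were protein-coding, 29 pseudogenes and 31 had a near-identical copy.

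Of the 102 genes, 90 were also called in at least 1 comparison with wild type and 34 in all 3 in the same direction, and the departure was opposite in sign to the change in 71 genes called for Scribble null, 72 for Yap1 Taz null and 37 for the triple null. A change of like size in all 3 null genotypes gives such a departure. As groups, oxidative phosphorylation had a median departure of 0.59 (0 and 0 over all genes, 9 and 0 adjusted over the list alone; adjusted p = 6.85e-13, adjusted p = 0.0346 with an estimated correlation) and interferon-induced genes one of 0.24 (8 and 0 over all genes, 15 and 0 adjusted over the list alone; adjusted p = 7.31e-09, adjusted p = 0.0346 with an estimated correlation). Immediate early genes had a median of −0.68 (0 and 5 over all genes, 0 and 17 adjusted over the list alone; adjusted p = 2.37e-10, adjusted p = 0.0846 with an estimated correlation), quiescence genes one of −0.44 (0 and 4 over all genes, 1 and 6 adjusted over the list alone; adjusted p = 0.00138, adjusted p = 0.191 with an estimated correlation) and G1/S genes one of 0.57 (0 and 0 over all genes, 6 and 0 adjusted over the list alone; adjusted p = 3.05e-08, adjusted p = 0.191 with an estimated correlation). Ribosomal protein and G2/M genes had medians of 0.32 (adjusted p = 4.76e-11, adjusted p = 0.254 with an estimated correlation) and 0.25 (adjusted p = 0.00178, adjusted p = 0.293 with an estimated correlation) with no member called over all genes or adjusted over the list alone. The unfolded protein response had a median of 0.29 (0 and 0 over all genes, 5 and 2 adjusted over the list alone; adjusted p = 0.00821, adjusted p = 0.236 with an estimated correlation). The monocyte, macrophage and dendritic list had a median of −0.09, a mean of 0.61 and a test upward (3 and 1 over all genes, 3 and 1 adjusted over the list alone; adjusted p = 0.0120, adjusted p = 0.202 with an estimated correlation). The median over all genes was −0.15. Camera called 9 of 32 lists, and 2 with an estimated correlation. The 102 genes fell to 44 and 53 without wild type 1 and 2, 60 without Scribble null 1, 56 and 48 without Yap1 Taz null 1 and 2, and 51 and 50 without triple null 1 and 2.

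Of the lists tied to the targeted pathways, Yap1/Taz targets and cell polarity did not pass camera in any comparison. By fry, Yap1/Taz targets passed in Scribble null, Yap1 Taz null and the departure from additivity (adjusted p = 0.0241, 0.0458 and 0.0440). Cell polarity, TGF-beta and BMP, Wnt, homing, lysosome and T and NK lists also passed fry in Scribble null, p53 in Yap1 Taz null and Wnt in the triple null. Fry does not set a list against all other genes. The median over all genes was itself 0.15, 0.14 and 0.12 in these genotypes and −0.15 in the departure, so a pass does not set a list apart from that shift. Of 32 Yap1/Taz target genes listed, 30 had values, with a median level of 1.55 TPM in wild type, and 19 passed the filter. Genes so low can hardly fall on the log2(TPM + 1) scale, so the lack of a call says little about them. The 19 tested had medians of 0.27, 0.24 and 0.21 in the Scribble null, Yap1 Taz null and triple null libraries against wild type (adjusted p = 0.338, 0.541 and 0.776), and Cyr61 was the only member called. Adjusted over the list alone, 2 were higher and 1 lower, then 0 and 0, then 1 and 1. The 36 cell polarity genes had medians of 0.18, 0.10 and 0.20 (adjusted p = 0.448, 0.867 and 0.369), with the frizzled receptor gene Fzd6 higher in Scribble null libraries by 1.74. TGF-beta and BMP genes (26) had adjusted p-values of 0.0674, 0.314 and 0.60, with Skil, Tgfb1 and Bmpr1a called in at least 1 comparison. They were, for Wnt (19) 0.454, 0.981 and 0.350, and for p53 (24) 0.955, 0.197 and 0.807. Homing and niche receptors (27) had adjusted p-values of 0.114, 0.782 and 0.369, although Itgb3, S1pr1 and Csf3r rose in Scribble null libraries. For glycolysis and hypoxia (28) the values were 0.0850, 0.258 and 0.247. They were, for lysosome and autophagy (31) 0.818, 0.355 and 0.807, and for apoptosis regulators (24) 0.721, 0.981 and 0.369. Markers of B cells (12), T and NK cells (11) and mast cells (8) had adjusted p-values of 0.822, 0.837 and 0.285, then 0.0850, 0.867 and 0.566, then 0.495, 0.969 and 0.546. None of these 12 lists passed camera in the 3 remaining comparisons either, where the lowest adjusted p-values were 0.0614 for TGF-beta and BMP genes against Scribble null, 0.0625 for p53 against Yap1 Taz null and 0.0631 for TGF-beta and BMP genes in the departure from additivity.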

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

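The tests of an MHC haplotype, of other cell types and of the offset between copies, and the repeat of the position test without interferon genes, were chosen only after the results were seen.

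The departure from additivity was called for 102 genes and 9 lists, which is a test of whether the change with loss of Scribble differs with and without Yap1 and Taz. With an estimated correlation 2 of the 9 lists were called, interferon response and oxidative phosphorylation. Among gene models with a name, the largest departures upward were Rpl10-ps3 at 6.79, Rpl3-ps1 at 6.60, Rps13-ps1 at 6.29 and Rpl35a-ps2 and Rpl35a-ps3, with 2 copies of the same values, at 5.81. Downward they were BC002163 at −6.78, whose size depends on the pseudocount because it is listed at 0 in the triple null, Klk1b22 at −5.86, Zfp69 at −3.95, Clec9a at −3.15 and Zfp990 at −2.97. Median departures of the lists were −0.44 for quiescence genes and cell cycle inhibitors, 0.57 for G1/S, 0.25 for G2/M, 0.24 for interferon response and −0.68 for immediate early genes. They were 0.32 for ribosomal proteins, 0.59 for oxidative phosphorylation, 0.29 for the unfolded protein response and −0.089 for monocyte, macrophage and dendritic markers. Of the 102 genes, 90 were also called in at least 1 comparison with wild type and 34 in all 3 comparisons with wild type in the same direction, where changes alike in size give a departure of that size with the opposite sign.

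By camera, the ribosomal protein and oxidative phosphorylation lists were lower in each null genotype than in wild type, by −0.40 against other genes over 91 members, although the called ribosomal members Rpl30 and Rps18 rose. With an estimated correlation the adjusted p was 0.160, 0.384 and 0.260 for ribosomal proteins and 0.0307, 0.0365 and 0.0743 for oxidative phosphorylation in Scribble null, Yap1 Taz null and triple null. Gene length is argued against as the whole cause, since removing its trend left a share of 0.788 of the gap (95% interval 0.751 to 0.838), and GC content likewise, with a share of 0.944 (0.930 to 0.992). A single wild-type library is argued against too, because at least 0.852 of the gap (0.785 to 0.919) was left without either. The genotype, as a hypothesis, and any other difference between wild-type and null animals stay open, since no test here separates them and the same 2 wild-type libraries enter all 3 gaps.

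The interferon list (adjusted p = 0.0307, 0.0365 and 0.0743 with an estimated correlation) and the MHC genes H2-Aa, H2-Ab1, H2-D1 and H2-K1 were lower in each null genotype than in wild type, while H2-T23 was called higher in each, H2-Ob in Scribble null and Yap1 Taz null, and H2-Eb1 in neither direction. A haplotype of the MHC region is argued against as the whole cause for the interferon list, since a share of 0.850 (0.615 to 1.002) of its gap was left with the 39 of 42 members outside chromosome 17 from 30 to 40 Mb, but it stays open for genes inside that region, where H2-Ea-ps was at 56.9 TPM in wild type and on average under 1 TPM in each null genotype. Monocytes or B cells in the wild-type libraries, which the stem cell sort would also remove, are argued against by 22 of their markers outside the MHC, whose median log2 change was 0.257 (0.010 to 0.438) where a fall of over 1 was needed, with Lyz2 at 212 and 256 TPM in wild type and 176 to 292 TPM elsewhere. Another strain background of the wild-type libraries cannot be told apart from the genotype. Of 46 genes called in at least 2 comparisons, 10 had another within 1 Mb, which met the bound set beforehand as 203 of 10000 draws had as many. Without interferon-list genes and Cd74, however, 4 of 39 did, where 3455 draws had as many. These genes were protein-coding, without a near-identical copy and outside chromosome 17 from 30 to 40 Mb. The test therefore does not cover H2-Ea-ps or the pseudogenes that were low in each null genotype. As a hypothesis, loss of the targeted genes may lower the interferon response to polyI:C, and this stays open as untested.

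Genes called against wild type that have a near-identical copy, Rps3a1 among them, formed 50 families. Reads divided differently between copies cannot be told apart from other causes by the summed change, which was a median 0.240 (0.121 to 0.393) of the gene's own, because any change of a minor member also gives a low ratio, although the bound set beforehand was met. Where the called gene moved by at least 20% of its family's summed TPM, copies offset a median share of 0.028 (−0.033 to 0.315) of its TPM change over 32 families, and 0.070 (−0.033 to 0.395) over 31 families that take in parent genes, which argues against an offset as the account for all of them. DNA of another strain around the targeted loci is argued against only within 20 Mb of them. There the odds ratio for calls, over genes with or without a copy, was 0.140 (0.004 to 0.788). Calls were 1 of 570 near and 572 of 46221 elsewhere (Fisher's exact p = 0.0120). Each gene is counted once for each locus, so this p and interval treat repeats of the same genes as independent. By locus, calls near were 1 of 133 for Wwtr1, 0 of 142 for Yap1 and 0 of 295 for Scrib. Rps3a1 lies 28.6 Mb from Wwtr1, outside that window, so the test does not cover it and this explanation stays open for it. An offset may still account for 8 families with shares above 0.5, among them Rps3a1, whose copies offset 0.615 of its change in Yap1 Taz null and 0.701 in the triple null.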

How the results depend on the processing

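The settings limited to protein-coding genes, without genes that have a near-identical copy, with the length trend removed, and with lists of protein-coding genes were chosen after seeing the data. A count test was not run, since there are no counts and TPM allows none to be recovered. Depth is unknown, and its limits could not be assessed.

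Counting a gene or list once for each comparison, of 234 calls of genes that the rule or the text names 86 kept their direction and their side of the threshold under all alternatives run, and of 63 calls of lists 6 did. Over all alternatives the called genes gave 2868 results that kept the call, 1075 that lost it and 0 that reversed, and the called lists 1030, 164 and 1. Of 191 uncalled results of genes that the rule names, 164 kept both, with 29 results newly called and 8 reversed. The correlations of fold changes moved by less than their jackknife SD of 0.173 to 0.177 under each alternative they were computed for, which are the pseudocounts, filters, scalings, the whole-series table and leave-one-out, with leave-one-out values of 0.496 to 0.723, 0.499 to 0.733 and 0.534 to 0.737. That SD is made from the leave-one-out values themselves, so for these the outcome was nearly fixed in advance. It is also wider than the gap between the correlations and the simulated 0.499, so it is a loose bound.

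For the counts of genes, the cause was not tested unless named. Without a filter, Scribble null against wild type gave 127 genes and triple null against Yap1 Taz null 17, with more genes tested. With only the groups compared, which leaves fewer libraries, the counts were 50, 56 and 58 for Scribble null, Yap1 Taz null and triple null against wild type, 11 for triple null against Scribble null and 6 against Yap1 Taz null. The departure from additivity uses all groups, so that setting is the same fit. Limma without the trend gave 100 for Scribble null and 62 for the departure. The whole-series table gave 101 for Scribble null, 105 for Yap1 Taz null, 20 for triple null against Scribble null and 15 against Yap1 Taz null. Protein-coding genes alone gave 54 for triple null against wild type and 16 against Scribble null, and leaving out genes with a copy gave 43, 17 and, for the departure, 63, both with fewer genes tested. Removing the length trend moved no count by over 1.5 times.

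The experiment numbers in the labels were tested as a replicate block. Same-numbered libraries of different genotypes deviated together with correlations from −0.053 to 0.026, so the numbers do not pair them. The block gave 110 genes for Scribble null against wild type and 14 for triple null against Yap1 Taz null, moved no other count by over 1.5 times, and left the lists called at 14, 7, 11, 10, 12 and 9.

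Camera with an estimated correlation called 2, 2, 0, 0, 0 and 2 lists in the 6 comparisons, in the order of the report, where 9, 3, 8, 6, 5 and 6 had an unadjusted p under 0.05. Fry called 21, 10, 11, 4, 2 and 7 lists.

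With a library left out, its group has 1 library, assumed to vary like the other groups. The counts of genes then ranged from 47 (without wild type 1) to 221 (without Scribble null 2) for Scribble null, from 53 to 134 for Yap1 Taz null, from 39 to 85 for the triple null, from 19 to 61 against Scribble null, from 9 to 21 against Yap1 Taz null and from 44 to 128 for the departure. The low end came without wild type 1 for each comparison with wild type and for the departure, without triple null 2 against Scribble null and without Yap1 Taz null 2 against Yap1 Taz null. Lists ranged from 10 to 16, 5 to 7, 9 to 12, 8 to 11, 3 to 11 and 8 to 11, and the low of 3 came without Yap1 Taz null 2.

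Among values that did not pass, Wwtr1 in Yap1 Taz null reversed to −0.086 with quantile normalization, −0.018 with median-ratio scaling and −0.044 without wild type 1 (range −0.044 to 0.295). Yap1 in the triple null reversed to −0.070 and −0.017 with these scalings. Without triple null 1, Scrib in the triple null reversed to −0.188 (range −0.188 to 0.672) and Wwtr1 to −0.132 (range −0.132 to 0.587). Gfi1b in Scribble null was 0.010 in the whole-series table. The ribosomal list against Yap1 Taz null reversed to −0.003 without Yap1 Taz null 2 (range −0.003 to 0.142). Ighj4 in Yap1 Taz null was 0.000 in the whole-series table, which has no direction and counts as a lost call. The cause of these reversals was not tested.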

Other observations

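All values in this part were chosen after they were seen. Genes called in all 3 comparisons with wild type, at an adjusted p under 0.05, also include the homeodomain factor gene Pbx4, at 11.4 ± 0.780 TPM in wild type against 41.4 ± 1.40, 38.1 ± 14.8 and 46.5 ± 4.23 TPM in the Scribble null, Yap1 Taz null and triple null libraries. Ivd, an enzyme of leucine breakdown, was at 68.7 ± 4.40 TPM against 165 ± 4.19, 137 ± 4.51 and 118 ± 2.90 TPM, and Eps8, an actin regulator, at 7.16 ± 0.688 TPM against 18.5 ± 0.516, 19.7 ± 0.132 and 23.3 ± 3.43 TPM. The class I gene H2-Q2 was lower, at 18.0 ± 1.74 TPM against 0.833 ± 0.151, 0.578 ± 0.437 and 0.507 ± 0.0477 TPM (SD, n = 2).

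Wild type 1 and Scribble null 1 had the lowest median correlation with the other libraries, at 0.939. Ribosomal protein genes took 16.1% and 14.7% of the TPM in the wild-type libraries and between 12.7% and 14.6% in the others.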
